A study of Mus musculus with 2 samples.

How the data were processed

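The series holds H3K27ac ChIP-seq from 2 replicates of newborn mouse liver (age 0 days), which form 1 group. Per the labels, both are mixed-sex pools of strain B6NTac;B6NCrl/Lap, replicate 1 from 15 mice and replicate 2 from a number of mice that the labels leave open, with a fragment size range of 300 to 500. Both came from the same tissue source and were immunoprecipitated in 1 laboratory, per the labels. They have different biosample entries but the same donor entry, so whether the animals were separate is not settled by the labels. They were taken as separate pools, and each SD over n = 2 rests on this and may cover technical spread only. Control libraries named in the labels were not analysed here.

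The authors deposited 4 lists of regions in the narrowPeak layout on mm10, per the text that accompanies the files: a list called on each replicate, a list called on both replicates together (pooled) and a list of replicated regions derived from the pooled list and both replicate lists. Every region of the replicated list was found with the same position in the pooled list. The deposited signal of a region is the authors' own measure of its enrichment. What it is relative to is not given in the sources used here, so it was used to describe and rank regions, in correlations between the replicate lists and in sums of signal × width. A test of the dose of X took it as proportional to dose. The lists also give −log10 p and −log10 q of each region and the position of its summit, as deposited. The peak caller, its threshold, the filters, the aligner and the replication criterion are not given in the sources used here. The deposited −log10 q was at least 2 for 75.6% of replicate 1 regions, 76.9% of replicate 2 regions, 83.9% of pooled regions and 98.2% of replicated regions, so the lists hold weak regions. Read depth is unknown, and no value here rests on read counts. Binomial intervals over regions are exact (Clopper-Pearson, 95%) and cover counting error only.

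From the lists, regions on chromosomes 1 to 19, X and Y were used. No list held the same position more than once. Coordinates are on GRCm38 (mm10) and counted from 1. Genes were taken from GENCODE M21 and sequence from GRCm38.p6. Regions of the replicate lists were called shared where the overlap covered at least 50% of either region. The observed share was set against 200 random placements of the other list on the same chromosomes, starting anywhere in sequence without unknown bases. TSS-proximal regions had at least 1 bp within 1 kb of an annotated TSS of a protein-coding gene, and the others were called exonic, intronic or intergenic in this order. The kept shares of TSS-proximal and distal pooled regions were compared by an odds ratio with a normal-approximation interval on its log.

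For gene lists, the bp covered by replicated regions within 25 kb on either side of the 5′-most protein-coding TSS were counted per gene. The median of a list was set against 10000 random lists of protein-coding genes of the same size (two-sided permutation test). Genes with a replicated region within 1 kb of any of their TSSs were counted and compared with all other protein-coding genes by Fisher's exact test. Benjamini-Hochberg adjustment was over the 27 lists, with a threshold of 0.05. The 27 lists, with 590 genes in all, cover hepatocyte secreted proteins, hepatocyte transcription factors, coagulation and complement, gluconeogenesis and amino acid breakdown, the urea cycle, fatty acid oxidation and ketogenesis, bile acid synthesis and transport, xenobiotic metabolism and fetal liver genes. They also cover erythroid, megakaryocyte, granulocyte and mast, macrophage and Kupffer, stem and progenitor, B and T or natural killer cells, sinusoidal endothelium, stellate cells and bile duct, cell cycle and housekeeping genes, and the absent tissues neuron, muscle, pancreas, intestine, lung and kidney, and germ line. Of the listed genes, 6 are in more than 1 list, and H19, Meg3, Ahsp and Amy2b stayed out because they were not matched as protein-coding genes in the annotation.

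TSS-distal regions at most 12.5 kb apart were joined into domains, ranked by the sum of signal × width, and called large above the point where the scaled rank curve has a slope of 1. This follows the usual ranking of clustered enhancers but uses the authors' region values and not reads. For 18 transcription factor words, occurrences on both strands per Mb of distal region were divided by those in windows of the same width starting 5 kb away that overlap no pooled region. The ratio was ranked among 200 letter-permuted words, or fewer where the word allows fewer (one-sided permutation test, Benjamini-Hochberg over the words). A fixed word is a crude stand-in for a binding motif. Genes with a TSS region in 1 replicate list only were to be compared between lists by Fisher's exact test, but in each list they were too few for any split to pass. The X ratio is regions per Mb on X over the median of the 19 autosomes.

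Genes were named by a fixed rule. It takes 30 fixed genes, the 3 members of each list with most coverage, members without a TSS region where a list has 5 or fewer, the 20 highest domains and the 10 regions with the highest signal. Members nearest to large domains and genes found in 1 replicate list were named after their values were seen. The samples, lists, words, tests, naming rule and alternatives were fixed before the data were examined. Among the exceptions are 8 gene lists, 2 alternatives and 8 tests of explanations, which were added later. Fisher's exact test of how often list members were nearest to a large domain was also not among the tests fixed beforehand. Alternatives covered the overlap, the −log10 q minimum (2 and 5), the 20000 strongest regions, scaffolds, the TSS and locus windows, matched random lists, distal regions alone, joining distance, flank distance, the summit alone, each replicate list alone and the pooled list.

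The overlap, locus, TSS and word computations were tested on simulated data, and the others were not. Overlap found 99.95% of planted regions and 0.00814% of the others among 98270 regions. The locus test on 21853 genes found 100% of planted lists and 0% of others, and the TSS test 100% and 1%. The word test found all planted words, and of 8 words not planted it called 1 (12.5%), CCNCNCCCN (KLF1). A call of that word would have been unsafe, and calls of other words may also include false ones. The simulated sequence had an even base composition in regions and flanks, so differences in composition between them were not tested. Values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures drawn with matplotlib 3.10.9. The text files that accompany the lists hold no measurements and were read only for how the lists were made.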

Results

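H3K27ac, a histone acetylation mark found at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the liver of newborn mice. At birth this organ holds both hepatocytes and blood-forming cells. There was 1 group with 2 replicates, each a mixed-sex pool of livers. They have different biosample entries but the same donor entry, so the labels leave open whether the animals were separate, and the spread between them may be technical. Replicate 1 was made from 15 mice, and the labels give no number of mice for replicate 2. The replicate 1 list held 100699 regions covering 55.7 Mb, or 2.04% of the genome, and the replicate 2 list held 110178 regions covering 63.3 Mb, or 2.32%. Regions called on both replicates together (the pooled list) numbered 104939 and covered 74.5 Mb. The 64382 pooled regions kept by the depositors as replicated covered 64.1 Mb, or 2.35% of the genome. The median width was 321 bp in replicate 1, 320 bp in replicate 2 and 641 bp in the replicated list. Read depth is unknown, because the lists give regions and not reads. The design holds no second condition, so the comparisons made were those between the replicates and those between genes, places and sequences within the lists.

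The first question was how far both pools of livers gave the same regions. Both lists held a region at the transcription start site (TSS) of 12128 protein-coding genes. Apoa1, which codes for the main protein of high-density lipoprotein, had a TSS signal of 17.2 in the replicate 1 list and 21.5 in the replicate 2 list, and Actb, the beta-actin gene, had 34.9 and 32.9. A region counted as shared where the overlap covered at least 50% of either region. Of the replicate 1 regions, 66483 of 100699 (66.0%, exact binomial interval 65.7 to 66.3%) were shared with replicate 2. Of the replicate 2 regions, 61799 of 110178 (56.1%, 55.8 to 56.4%) were shared with replicate 1. Regions placed at random on the same chromosome gave means of 3.80% and 3.46%, with maxima of 4.00% and 3.70% over 200 placements. Both two-sided permutation p-values were 0.00995, the smallest that 200 placements can give. Sharing fell with rank: 99.98% of the strongest 10% of either list was shared, against 30.9% of the weakest 10% of replicate 1 and 20.2% of the weakest 10% of replicate 2. Over 45198 pairs of regions that matched each other alone, the signal ranks correlated with a Spearman rho of 0.710 and the log2 signals with a Pearson r of 0.848, across regions, which are not independent replicates. Where the overlap had to cover 50% of both regions, the shares were 41.6% and 38.0%.

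**Figure D1:**
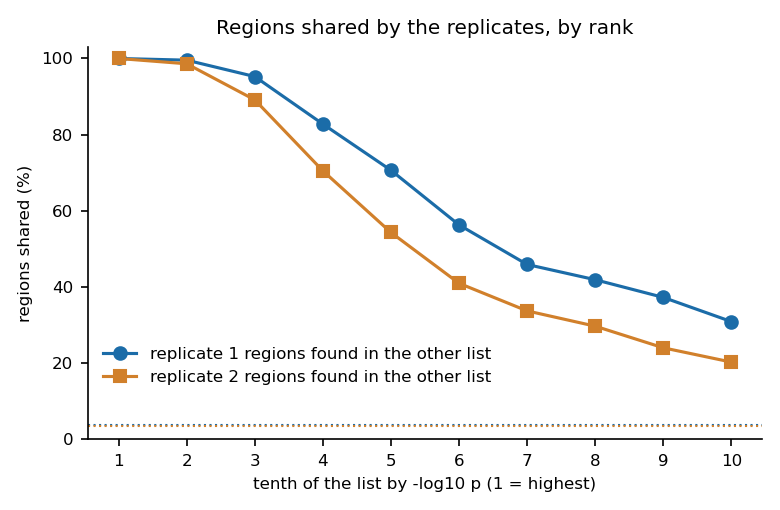
The percent of regions shared with the other replicate (vertical axis) is plotted for 10 equal parts of a replicate list ordered by −log10 p (horizontal axis, 1 is the highest), with replicate 1 as circles, replicate 2 as squares and the means of randomly placed regions as dotted lines. The curves start at 99.98% and end at 30.9% for replicate 1 and 20.2% for replicate 2, above the dotted lines at 3.80% and 3.46%.

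The next comparison was between promoters and the rest of the genome. Regions within 1 kb of the TSS of a protein-coding gene were kept by the depositors more often than distal regions: 18512 of 23610 TSS-proximal pooled regions (78.4%) were in the replicated list, against 45870 of 81329 distal regions (56.4%). The odds ratio was 2.81 (95% interval 2.71 to 2.90), from counts of regions, which are not independent replicates. Of all pooled regions, 61.4% (61.1 to 61.6%) were kept, and of those with a −log10 q of at least 5, 96.8% were. With the overlap of 50% of both regions in place of the depositors' criterion, 34.3% of pooled regions were in both replicate lists. TSS-proximal regions made up 28.8% of the replicated list (exact binomial interval 28.4 to 29.1%), 5.04-fold the 5.71% of randomly placed regions. Introns held 39.9% (1.16-fold), exons 3.36% (1.27-fold) and intergenic sequence 27.96% (0.489-fold). Each of these shares had a two-sided permutation p of 0.00995, the smallest possible. TSS-proximal regions were wide and strong, with a median width of 1011 bp and a median signal of 7.95, against 554 bp and 4.25 in introns and 581 bp and 4.60 in intergenic sequence. Of 21853 protein-coding genes, 12202 (55.8%) had a replicated region at a TSS. This share was 57.3% in the replicate 1 list and 57.7% in the replicate 2 list.

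Genes of hepatocytes, the main epithelial cells of the liver, lay in windows rich in H3K27ac. The 29 genes of secreted plasma proteins had a median of 14.2 kb covered by replicated regions within 25 kb on either side of the TSS, which was 7.30-fold the median of random gene lists. The median was 12.8 kb in replicate 1 and 14.5 kb in replicate 2 (mean 13.6 ± 1.199 kb, SD, n = 2). The urea cycle genes followed with 11.8 kb (5.78-fold; 8 genes), gluconeogenesis and amino acid breakdown with 9.84 kb (5.07-fold; 20 genes) and hepatocyte transcription factors with 9.70 kb (4.91-fold; 20 genes). Fatty acid oxidation and ketogenesis reached 7.69 kb (3.97-fold; 20 genes), bile acid synthesis and transport 7.32 kb (3.70-fold; 18 genes), and coagulation and complement 6.79 kb (3.47-fold; 28 genes). The median over all protein-coding genes was 1.94 kb of the 50 kb window, and 6825 genes had none. All 7 of these hepatocyte lists passed the two-sided permutation test against 10000 random lists of the same size, with adjusted p from 0.00108, the smallest seen, to 0.0020 over 27 lists. The smallest unadjusted p that the random lists can give is 0.0002. Neighbouring members, such as Apoc1 and Apoe, share covered bases, while random lists were drawn from genes at any position. The test takes members as independent, so its p-values may be too small for lists with clustered genes. The coagulation and complement call was lost when TSS-proximal regions were left out (permutation, adjusted p = 0.113; range over 7 alternatives 0.000675 to 0.113). The bile acid call was lost with a window of 50 kb on either side (permutation, adjusted p = 0.109; range 0.000675 to 0.109).

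Single hepatocyte genes showed the range within these lists. Apoc1 and Apoe, which code for apolipoproteins and lie side by side on chromosome 7 (TSSs at 19692660 and 19699188, GRCm38), had 34.4 and 31.8 kb covered, and a region of 12.52 kb (19690860 to 19703379) spanned both TSSs. Fga, a fibrinogen chain gene, had 28.3 kb and Apoa1 19.6 kb. Alb, the albumin gene (chromosome 5, TSS at 90460897), had 13.4 kb covered, 9.09 kb in replicate 1 and 14.7 kb in replicate 2. Within 1 kb of this TSS lay 4 replicated regions. The one with the highest signal (90460021 to 90460622) was 0.602 kb wide and had a signal of 4.71. This is at percentile 49.0 of all replicated regions, and below the median of 7.95 for TSS-proximal ones. Afp, the alpha-fetoprotein gene just downstream (TSS at 90490737), had 8.62 kb covered but no replicated TSS region. Each replicate list held a weak region at an annotated Afp TSS, with signals of 3.12 and 3.52. Replicate 2 had one within 1 kb of the TSS at 90490737 (90491268 to 90491508), and replicate 1 had none there. Apoa4, Serpina6 and Serpina3k also had no replicated TSS region, so that 25 of the 29 secreted protein genes had one (86.2%, against 55.8% of other genes; Fisher's exact test, two-sided, adjusted p = 0.00235).

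**Figure D2:**
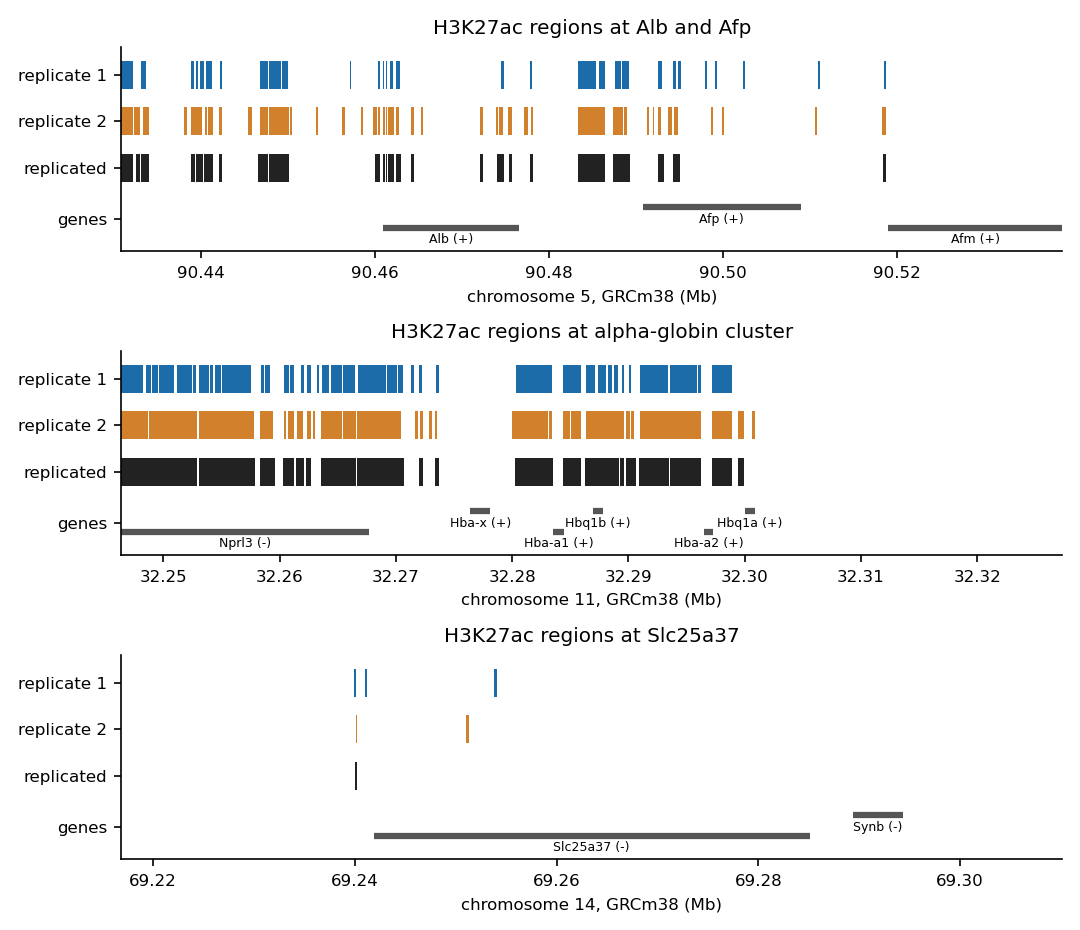
Regions of the replicate 1, replicate 2 and replicated lists are drawn as bars along GRCm38 positions in Mb (horizontal axis) above the genes of 3 loci, those of Alb and Afp, the alpha-globin cluster and Slc25a37. Bars cover 13.4 kb of the 50 kb around the Alb TSS and 26.99 kb around Hba-a1, and none of the 50 kb around the Slc25a37 TSS.

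The factors that set hepatocyte gene expression had acetylated promoters without exception: 20 of 20 had a replicated TSS region (Fisher's exact test, two-sided, adjusted p = 4.1e-05). Foxa3 had 19.5 kb covered, Nr1i3 17.5 kb and Cebpa 16.2 kb, with a TSS signal of 18.99 at Cebpa. Foxa2 had 7.48 kb and a TSS signal of 15.2. Hnf4a, the main nuclear receptor of hepatocyte identity, had only 0.322 kb around its 5′-most TSS (chromosome 2, 163506808), while a region 3.74 kb wide with a signal of 13.7 lay at another of its TSSs (163547089 to 163550823). Locus coverage counted from the 5′-most TSS therefore missed the acetylated Hnf4a promoter.

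Metabolic genes had TSS regions nearly throughout. Pck1, which codes for the rate-limiting enzyme of gluconeogenesis, had a TSS signal of 20.7 and 14.0 kb covered, and Tat, the tyrosine aminotransferase gene, had 9.19 and 9.33 kb. Hpd, Fbp1 and Slc37a4 had the most coverage among the gluconeogenesis and amino acid genes, with 16.5, 14.4 and 14.2 kb. Of these 20 genes, 19 had a TSS region (adjusted p = 0.00042, Fisher's exact test, two-sided), with Tdo2 as the exception. In the urea cycle, Slc25a13, Ass1 and Arg1 had 19.2, 14.5 and 13.6 kb, Cps1 had 10.7 kb, and 8 of 8 genes had a TSS region (adjusted p = 0.0184, Fisher's exact test). Among genes of fatty acid oxidation and ketogenesis, Hmgcl, Acox1 and Hmgcs2 had 14.9, 14.7 and 13.9 kb, and Cpt1a, which controls fatty acid entry into mitochondria, had a TSS signal of 17.0. Here 19 of 20 genes had a TSS region (adjusted p = 0.00042, Fisher's exact test), without Fgf21. Cyp8b1, Abcc2 and Hsd3b7 led the bile acid genes with 16.6, 16.4 and 14.3 kb. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had 3.60 kb and a TSS signal of 6.11, and Slco1a1 and Cyp7b1 had no replicated TSS region (16 of 18 genes with one, adjusted p = 0.0069, Fisher's exact test). Serpinf2, Masp1 and C3 led coagulation and complement with 27.96, 17.1 and 14.9 kb, and 26 of 28 genes had a TSS region (adjusted p = 9.1e-05, Fisher's exact test), without Mbl2 and C9.

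The 2 other hepatocyte lists did not differ from random lists. Xenobiotic cytochrome P450 and conjugation genes had a median of 2.68 kb (1.36-fold, permutation, adjusted p = 0.590), and 14 of 26 had a TSS region (53.8%; Fisher's exact test, adjusted p = 0.846). How far sequence at these genes is copied elsewhere in the genome was not checked, so absent regions may reflect reads that cannot be placed. Por, the electron donor of these enzymes, had 14.9 kb, Fmo5 11.01 kb and Gsta3 8.58 kb. Cyp3a11 had a TSS signal of 16.3 with 3.24 kb covered, and Cyp2e1 a signal of 4.998 with 2.72 kb. Fetal liver genes that are silenced after birth had a median of 2.74 kb (1.41-fold, permutation, adjusted p = 0.633), and 9 of 15 had a TSS region (60.0%; Fisher's exact test, adjusted p = 0.846). The latter share was 73.3% in the replicate 1 list and 80.0% in the replicate 2 list. Grb10 had 12.6 kb and Igf2bp3 12.1 kb, and the growth factor gene Igf2 had a TSS signal of 11.03 with 6.67 kb. The Igf2 signal was that of a region (142658103 to 142661862) at another annotated TSS than the 5′-most one (142666816). The imprinted noncoding genes H19 and Meg3, which stayed out of the test, had 20.97 and 3.63 kb covered, with TSS signals of 7.11 and 3.91.

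**Figure D3:**
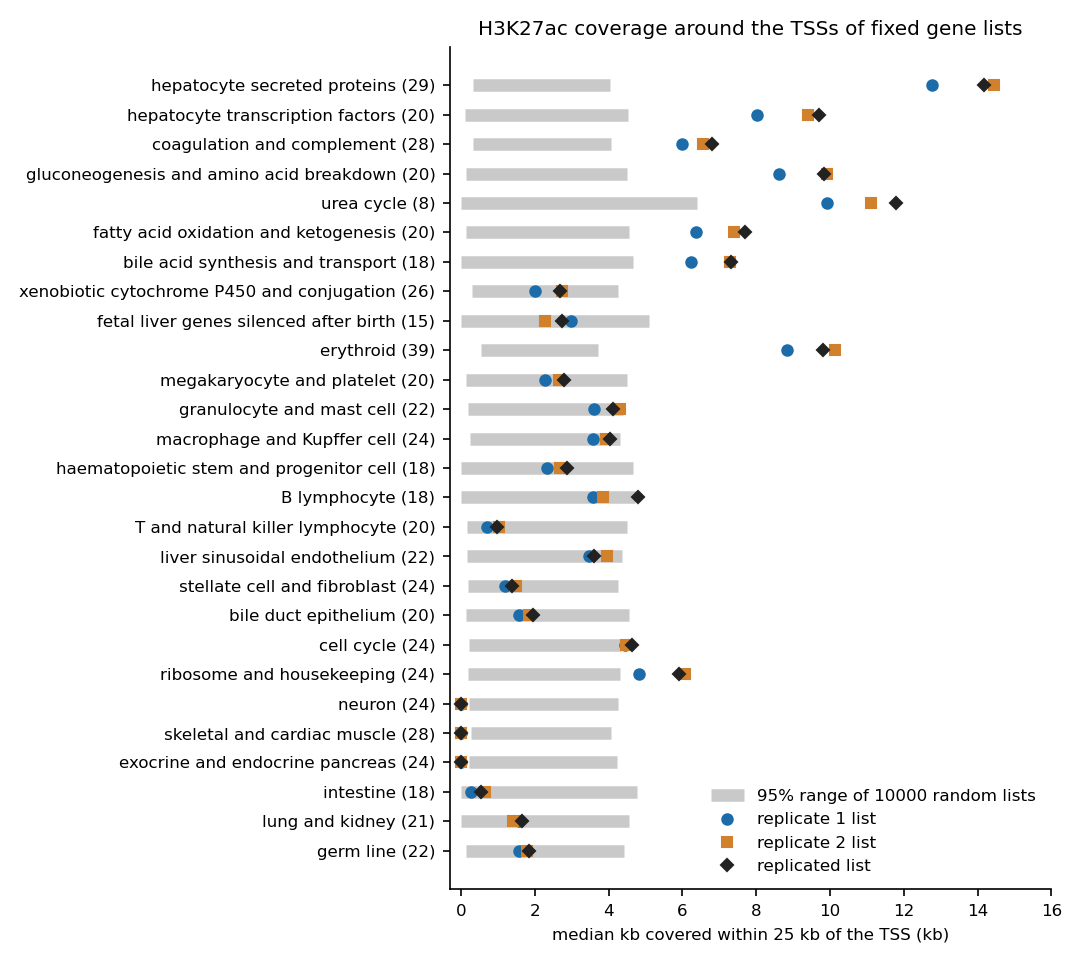
Median kb covered within 25 kb of the TSS (horizontal axis) is plotted for the 27 gene lists (rows, number of tested genes in brackets), with replicate 1 as circles, replicate 2 as squares, the replicated list as diamonds and the 95% range of 10000 random lists as grey bars. Secreted proteins reach 14.2 kb and erythroid genes 9.82 kb, and the neuron, muscle and pancreas lists sit at 0.

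Among blood lists, the erythroid list passed the locus test in the replicated list, and its difference from the other blood lists was not tested. Its 39 members had a median of 9.82 kb covered, 5.08-fold the random median, with 8.84 kb in replicate 1 and 10.1 kb in replicate 2 (mean 9.48 ± 0.911 kb, SD, n = 2; permutation, two-sided, adjusted p = 0.00108). The alpha-globin cluster on chromosome 11 was acetylated over most of its length: Hba-x (TSS at 32276400) had 33.5 kb of its window covered and Hba-a1 (TSS at 32283511) 26.99 kb, with a signal of 17.7 at the Hba-a1 TSS. Words of 31 bases within 1 kb of the Hba-a1 TSS occurred in more than 1 copy of the genome in 75.0% of cases, so reads there cannot always be placed. In the beta-globin cluster on chromosome 7, Hbb-bt had a TSS signal of 8.20 and 12.4 kb covered. Windows of neighbouring globin genes overlap, so the same regions count for several erythroid members and the locus p may be too small. The embryonic globin genes Hba-x, Hbb-y and Hbb-bh1 had no replicated TSS region, although Hbb-y and Hbb-bh1 had 20.1 and 15.6 kb of their windows covered. Replicate 2 alone held a TSS region at Hbb-y, with a signal of 3.81. The erythroid factor genes Klf1, Nfe2 and Gata1 had 10.7, 21.3 and 8.24 kb, with TSS signals of 19.8, 15.3 and 5.41. The Gata1 signal was that of a region (7967915 to 7969560) at another annotated TSS than the 5′-most one (7978071). In all, 35 of 39 erythroid genes had a TSS region (89.7%; Fisher's exact test, two-sided, adjusted p = 2.8e-05), and Slc25a37, the iron importer of erythroid mitochondria, had neither a TSS region nor any coverage.

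The remaining blood lists did not pass the locus test, although the windows of single genes in them were well covered. Regions at the TSSs of neighbouring genes count in a window too. At Gp1ba, for example, distal regions gave only 356 bp and its strongest TSS region 1466 bp of the coverage. Granulocyte and mast cell genes had a median of 4.11 kb (permutation, adjusted p = 0.129), with 12.3 kb at S100a8, 10.8 kb at Lcn2 and 10.7 kb at Fcnb. Macrophage and Kupffer cell genes had 4.03 kb (permutation, adjusted p = 0.129), with 19.4 kb at Fcer1g, 17.6 kb at Spi1 and 13.5 kb at Aif1, while the Kupffer cell receptor gene Clec4f had 0.959 kb and no TSS region. The Fcer1g window overlapped that of the hepatocyte gene Nr1i3. B lymphocyte genes had 4.797 kb (permutation, adjusted p = 0.0856), with 12.47 kb at Cd79a, 10.1 kb at Spib and 9.69 kb at Vpreb3. Megakaryocyte and platelet genes had 2.79 kb (permutation, adjusted p = 0.590), with 13.8 kb at Nbeal2, 13.3 kb at Gp1ba and 11.5 kb at Fli1. Stem and progenitor cell genes had 2.88 kb (permutation, adjusted p = 0.590), with 22.1 kb at Lyl1, 14.9 kb at Lmo2 and 10.1 kb at Ikzf1. T and natural killer lymphocyte genes had 0.971 kb (permutation, adjusted p = 0.469), with at most 8.10 kb at Lck and 3.404 kb at Cd3d and Cd3g.

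By TSS regions, T and natural killer genes were below other genes, with 4 of 20 (20.0%; Fisher's exact test, two-sided, adjusted p = 0.0026). The other non-erythroid blood lists did not differ in the replicated list. TSS regions lay at 12 of 20 megakaryocyte, 13 of 22 granulocyte, 16 of 24 macrophage, 12 of 18 progenitor and 13 of 18 B lymphocyte genes. Each of these shares was higher in both replicate lists, with granulocyte genes at 63.6% in replicate 1 and 77.3% in replicate 2. The B lymphocyte genes without one were Cd22, Rag1, Rag2, Dntt and Ms4a1. The granulocyte call depended on the window, and was gained with 10 kb, with 50 kb and with distal regions alone (permutation, adjusted p over 7 alternatives 0.0072 to 0.149). The B lymphocyte call was gained with 10 kb and with distal regions alone (0.00648 to 0.491), and the macrophage call in the pooled list alone (0.0490 to 0.662).

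The lists of other liver cell types did not pass the locus test in the replicated list. Sinusoidal endothelial genes had a median of 3.60 kb (permutation, adjusted p = 0.260), with 23.0 kb at Egfl7, 14.7 kb at Stab1 and 14.2 kb at Lyve1, and Stab2 had 2.59 kb and a TSS signal of 4.62. Their call was gained with a window of 10 kb and with distal regions alone (permutation, adjusted p over 7 alternatives 0.00463 to 0.484). TSS regions were present at 17 of 22 of these genes (77.3%; Fisher's exact test, adjusted p = 0.0784), and the replicated list had none at Sox18, Flt1, Tek, Flt4 and Wnt2. The share was 81.8% in the replicate 1 list and 95.5% in the replicate 2 list, against 57.3% and 57.7% of all protein-coding genes. With these lists in place of the replicated one, 11 and 12 gene lists had more TSS regions in this test, against 10. Stellate cell and fibroblast genes had 1.37 kb (permutation, adjusted p = 0.633), with 8.15 kb at Tagln, 5.48 kb at Colec11 and 5.36 kb at Reln. Col1a1, a collagen gene, had 1.11 kb and a TSS signal of 3.31, at percentile 13.4 of all replicated regions. Of the stellate genes, 16 of 24 had a TSS region (Fisher's exact test, adjusted p = 0.382). Bile duct genes had 1.94 kb (permutation, adjusted p = 0.971), with 12.1 kb at Cdh1, 6.03 kb at Cldn7 and 4.56 kb at Sox4, and none at the duct keratin gene Krt19. TSS regions were found at 8 of 20 bile duct genes (40.0%; Fisher's exact test, adjusted p = 0.255).

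Genes used by most cells had TSS regions nearly throughout. Of the ribosome and housekeeping genes, 24 of 24 had one (Fisher's exact test, two-sided, adjusted p = 6.3e-06), and the median coverage was 5.91 kb (3.01-fold; permutation, adjusted p = 0.0150). Actb had a TSS signal of 46.8, at percentile 99.9 of all replicated regions, and 19.5 kb covered. Ubc had 15.2 kb and Rplp0 14.0 kb. Of the cell cycle genes, 23 of 24 had a TSS region (95.8%; Fisher's exact test, adjusted p = 9.1e-05), without the mitotic checkpoint gene Bub1. Their coverage of 4.64 kb missed the threshold (permutation, adjusted p = 0.0665), with 14.6 kb at Aurkb, 11.5 kb at Rrm2 and 10.1 kb at Mcm7. It passed with a window of 10 kb and in the replicate 1 list (adjusted p over 7 permutation alternatives 0.0152 to 0.584).

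Genes of tissues other than liver mostly lacked TSS regions. The counts were 1 of 24 neuron, 2 of 28 muscle, 2 of 24 pancreas, 3 of 18 intestine, 6 of 21 lung and kidney and 1 of 22 germ line genes, each fewer than among other genes (Fisher's exact test, two-sided, adjusted p from 1.3e-06 to 0.0232). Neurod1, Myod1 and Ins2 had no TSS region and no coverage, and the germ cell gene Ddx4 had no TSS region and 2.04 kb. The neuron, muscle and pancreas medians were 0 kb, intestine 0.532 kb, lung and kidney 1.66 kb and germ line 1.86 kb. None of these 6 passed the locus test in the replicated list (permutation, adjusted p from 0.0665 to 0.957). The neuron, muscle and pancreas lists were lower in each replicate list and in the pooled list, and neuron also with a window of 50 kb (permutation, adjusted p over 7 alternatives 0.0144 to 0.863 for neuron, 0.0299 to 0.863 for muscle and 0.0333 to 0.863 for pancreas). Their medians in both replicate lists were again 0, so passing there does not reflect a lower median. Single members lay in covered windows: Mymx had 17.8 kb, Mylpf 17.7 kb and Tnni2 6.08 kb among muscle genes, and Cela1 12.53 kb, Rbpjl 4.70 kb and Ctrb1 3.63 kb among pancreas genes. Slc17a7 had 4.59 kb, Syn1 1.80 kb and Grin1 1.73 kb among neuron genes. Apoa4, which is also in the secreted protein list, had 20.1 kb, Vil1 9.25 kb and Cdx2 3.11 kb among intestine genes. Ager, Sftpa1 and Sftpc had 12.4, 11.6 and 11.3 kb, and Nanos2, Zp3 and Nanos3 had 9.98, 6.98 and 6.30 kb. A window also counts regions of neighbouring genes, as at Nanos2, whose window overlapped that of Foxa3.

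Distal regions were then joined into domains to find where they cluster. The domain with the highest summed signal × width was near Irs2, which codes for an adaptor of the insulin receptor (chromosome 8, 10849854 to 11022130), and held 42 regions over 172 kb. Next came a domain of 59.3 kb on chromosome 19 (5792733 to 5851996) that contains the noncoding genes Malat1 and Neat1 and whose nearest protein-coding TSS was that of Scyl1. Domains nearest to Zmiz1, Tomm20, Sema4b, Bcl2l1, Chd2, Supt4a, Elmsan1, Mtss1, Agpat4, Cmip, Eed, Wdr26, Btg2, E030018B13Rik, Zfp36l2, Bysl, Irf2bpl and Cyb5a completed the highest 20, and all 20 were also large in both replicate lists. The 45870 distal regions formed 16139 domains, of which 920 (5.70%) lay above the point where the rank curve reaches a slope of 1. These large domains had a median width of 31.004 kb, a median of 9 regions and 41.2% of the summed signal × width. Replicate 1 had 1220 large domains, of which 982 (80.5%) overlapped a large domain of replicate 2, and replicate 2 had 1103, of which 970 (87.9%) overlapped. Without joining, 2014 regions lay above the same point. Distal here means distant from protein-coding TSSs, so promoters of noncoding genes count as distal.

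Among genes nearest to a domain, members of 4 of the 9 hepatocyte lists and of the erythroid list were nearest to a large domain more often than other genes, at 9.34 to 9.37%. The share was 4 of 7 urea cycle genes (57.1%; Arg1, Ass1, Cps1 and Slc25a13), 7 of 14 gluconeogenesis and amino acid genes (Aldob, Fbp1, G6pc, Hpd, Pck1, Ppargc1a and Tat) and 7 of 17 hepatocyte transcription factors (41.2%; Cebpa, Cebpb, Nr0b2, Nr1i2, Nr5a2, Ppara and Prox1). It was 7 of 21 secreted protein genes (33.3%; Alb, Apoa1, Apob, Apoc1, Fga, Hp and Trf) and 8 of 24 erythroid genes (33.3%; Ank1, Car2, Gypa, Hbb-y, Rhd, Slc4a1, Sptb and Zfpm1). Fisher's exact test, two-sided, gave adjusted p from 0.00325 to 0.0122 for these 5 lists, over a background of 9210 genes. This test was not among those fixed beforehand. Stem and progenitor genes (4 of 14; Erg, Etv6, Ikzf1 and Lmo2) had an adjusted p of 0.163 in Fisher's exact test. The other 5 hepatocyte lists did not pass (Fisher's exact test, adjusted p from 0.533 to 1), with 3 of 22 coagulation and complement, 3 of 14 fatty acid, 2 of 15 bile acid, 1 of 15 xenobiotic and 1 of 13 fetal liver genes, and the remaining lists did not pass either.

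Of the 10 regions with the highest signal, 8 lay at a TSS. The highest signal, 75.97, was at the TSS of Pnrc1 (chromosome 4, 33245968 to 33249943), and the next, 72.8, was intergenic and nearest to Sirt4 (chromosome 5, 115488334 to 115492507). Ggnbp2, Dyrk1a, Kmt2e, Ankrd11, Elf1 with Wbp4, Zc3h4 and Msl2 had TSS regions with signals of 68.5, 62.8, 62.6, 60.8, 59.7, 58.9 and 58.1, and an intergenic region nearest to Arid1a had 62.1. None of these genes is in a list fixed beforehand.

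Sequence words bound by named transcription factors were then counted in the 45870 distal regions and in 66836 flanking windows. Words of hepatocyte and blood factors were more frequent in the regions: HNF4A 1.70-fold (882 occurrences), FOXA 1.32-fold (6947), CEBPA 1.89-fold (63), GATA 1.25-fold (6386), GATA-TAL1 1.79-fold (731), SPI1 1.93-fold (600) and RUNX 1.14-fold (3352). HNF1A was 3.88-fold more frequent, with only 7 occurrences in regions and 2 in flanks. The ETS word, used in many tissues, was 1.86-fold more frequent, and the muscle factor word MEF2 1.28-fold (106 occurrences). These 10 of 18 words passed a one-sided permutation test against at most 200 letter-permuted words each (adjusted p from 0.0299 to 0.0448). The other 8 did not pass, namely ONECUT1 (1.03-fold), KLF1 (1.25-fold), NFE2 (1.59-fold), NRF1 (1.18-fold), CTCF (0.295-fold, 6 occurrences), POU5F1-SOX2 (0.746-fold), NEUROD1 (1.28-fold) and MYOD1 (1.26-fold). The word counted under POU5F1-SOX2 was ATGCAAAT alone, and no longer joint motif was counted. In the replicate lists, each word tested alike, HNF1A, RUNX and MEF2 passed in 1 list only, with HNF1A at 1.77-fold in replicate 1 and 2.16-fold in replicate 2. CEBPA and RUNX did not pass with flanks starting 20 kb away, and HNF1A, ETS and MEF2 did not pass in regions with a −log10 q of at least 5. No word passed in the 200 bp around the summit, where HNF4A was at 1.07-fold, FOXA at 1.06-fold, GATA at 1.096-fold and HNF1A at 0.945-fold. GATA exceeded all its permuted words there and FOXA nearly all. Their p-values of 0.00952 and 0.00995 adjusted to 0.0896 over the 18 words (one-sided permutation).

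**Figure D4:**
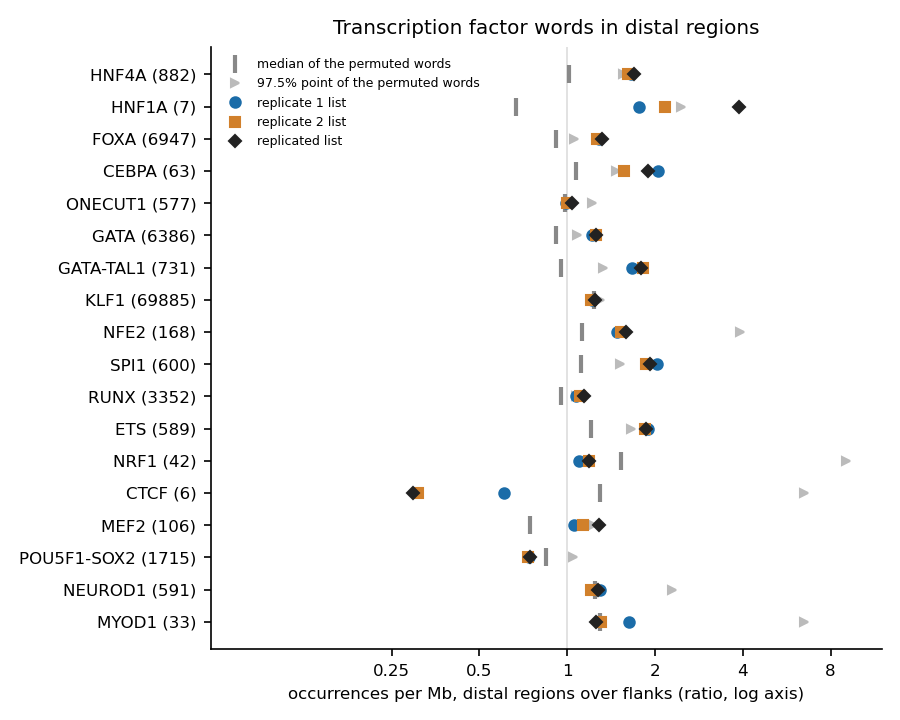
The ratio of word occurrences per Mb in distal regions over flanks (horizontal axis, log scale) is plotted for 18 transcription factor words (rows, occurrences in the replicated list in brackets), with replicate 1 as circles, replicate 2 as squares, the replicated list as diamonds, and the median and the upper end of the 95% range of permuted words as grey marks. HNF4A lies at 1.70, SPI1 at 1.93 and GATA-TAL1 at 1.79, and CTCF at 0.295.

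Some genes had a TSS region in 1 replicate list only, 384 in replicate 1 and 475 in replicate 2. Among granulocyte genes, Elane, Mpo and Retnlg were in replicate 2 alone and none in replicate 1 alone. Among endothelial genes, Tek, Tie1, Wnt2 and Flt4 were in replicate 2 alone and Sox18 in replicate 1 alone. With at most 5 such genes in any of the 27 lists, no split could pass Fisher's exact test (two-sided; smallest possible adjusted p 0.343), so whether the pools differed by cell type stayed open.

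The X chromosome, present in both sexes of the mixed pools, held few regions. It had 5.99 replicated regions per Mb, against a median of 26.3 per Mb over the 19 autosomes (range 18.6 to 41.3), a ratio of 0.228. The ratio was 0.214 in replicate 1 and 0.213 in replicate 2, and the Y chromosome had 3 replicated regions. X held 1.08 regions per protein-coding gene, against 2.05 to 3.90 on the autosomes, and 35.0% of X genes had a TSS region. Gata1, an X-linked erythroid gene (TSS at 7978071), was among the covered ones with 8.24 kb. The difference in density was not tested for significance, since X is a single chromosome, and explanations for it are examined further below. The part of X sequence in 1 copy (69.1% of sampled words of 31 bases) was lower than on the autosomes (77.8 to 88.3%).

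**Figure D5:**
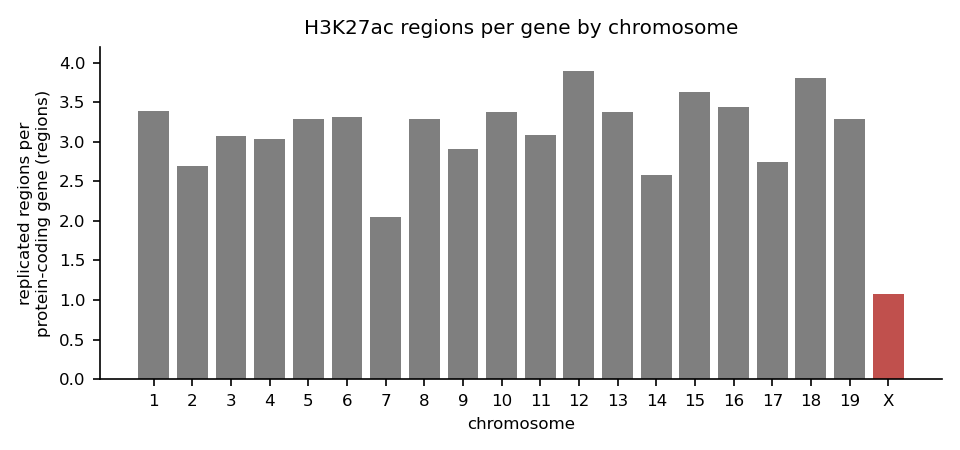
Bars give the number of replicated regions per protein-coding gene (vertical axis) for each autosome and X (horizontal axis). X stands at 1.08, below the lowest autosome, chromosome 7, at 2.05.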

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

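The tests of gene density on X and of random windows against summits were chosen only after their results were seen. The remaining tests of explanations in this part were set out before their results were seen.

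Regions on sequences outside chromosomes 1 to 19, X and Y entered no comparison of the report and only 1 alternative, and their number passed the 3 entries that a count of 0 allows. There were 9 in the replicate 1 list (0.00894% of entries), 8 in the replicate 2 list (0.00726%), 8 in the pooled list (0.00762%) and 7 in the replicated list (0.0109%). No explanation was tested.

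The X chromosome had 0.228 times the region density of the autosomes. A lower number of genes cannot be the whole cause, since X had 1.08 regions per protein-coding gene and the autosomes 2.05 to 3.90. Sequence that short reads cannot place also falls short, with 9.08 regions per Mb of sequence in 1 copy on X against 23.4 to 48.2 on the autosomes. A lower dose of acetylated X, with 1 copy in males and 1 inactive copy in females, stays a candidate explanation if the signal is proportional to dose, which the files do not show: X regions per gene above the median X signal of 5.08, over autosomal regions per gene above 10.2, gave a ratio of 1.04, inside the 0.704 to 1.25 of single autosomes. Fewer X regions of unchanged strength could give the same ratio, so the test cannot tell this from a lower dose. The median X signal was also not below the 4.81 of all replicated regions. Whether X genes of the liver are fewer or less active was not tested, so a lower dose is a hypothesis only.

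Transcription factor words were more frequent in whole distal regions (10 of 18 words) than around the summits (0 of 18). A window of 200 bp drawn at random inside each region also gave 0 words, so the small window or its equal weight for narrow regions may account for the lost calls. The count of 0 does not mean that no word stood out. In these windows FOXA (p = 0.00498) and GATA (p = 0.00952) exceeded all their permuted words, but each adjusted to 0.0857 over the 18 words (one-sided permutation). The ratios there stayed nearer to those of whole regions (FOXA 1.23-fold, GATA-TAL1 1.68-fold, CEBPA 1.70-fold, HNF4A 1.30-fold) than those around the summit did (1.06, 1.24, 0.875 and 1.07-fold). Whether a window of 200 bp anywhere in the region accounts for the lower ratios stayed open: in a median of 1.5 of the 10 words over 10 draws, random windows were richer than the summit beyond the 95% range of permuted words, between the 1 and 5 set as bounds. Summits on acetylated nucleosomes beside the factor sites cannot be told apart from this, because 4 of the 10 words (CEBPA, GATA, SPI1 and ETS) were richer 150 to 350 bp from the summit than within 100 bp, beyond the 95% range of their permuted words, between the 1 and 5 set as bounds. That test used the 24804 regions wide enough for it. No further biological explanation was tested.

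Among the 9 gene lists that passed the locus test, 14 members had no replicated TSS region. Some of them had a weak TSS region in a replicate list. Afp (signals of 3.12 and 3.52) and Apoa4 (2.73 and 3.59) had one in both. Serpina3k (3.13) and Hbb-y (3.81) had one in replicate 2 alone, and Cyp7b1 (3.08) in replicate 1 alone. Sequence copied elsewhere in the genome cannot explain most of the 14 absences: 1 of 14 (7.14%) had over 50% copied words at the TSS, against 3 of 192 other members (Fisher's exact test, two-sided, p = 0.247). The 1 member was Slc25a37, where 100% of the words in the 50 kb window (chromosome 14, 69260112 to 69310112) occur in more than 1 copy, with copies at 69470001 to 69530000, so its empty window may be a gap in read placement. Copies did not always remove regions, since Hba-a1 (75.0%), Hba-a2 (81.0%) and Serpina1a (57.9%) had TSS regions. For the embryonic globin genes Hba-x, Hbb-y and Hbb-bh1, silence at birth remains an untested biological explanation, although Hbb-y had a TSS region in the replicate 2 list.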

How the results depend on the processing

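The definition of the added alternative on pooled regions and that of permuted words with the same number of CG were chosen only after the results were seen. Over all alternatives tried, 9 to 13 gene lists lay above random lists, 10 to 12 had more TSS regions, 7 to 10 words passed except around the summit, 803 to 1220 domains were large except without joining, and the odds ratio ran from 1.81 to 4.06. Shared regions moved with the overlap, by construction, and these and the share kept moved with the threshold, in the order replicate 1, replicate 2 and pooled. For pooled regions, the overlap alternatives also replaced the depositors' list with presence in both replicate lists. An overlap of at least 1 bp gave 72.6%, 62.3% and 54.7%, and 50% of both regions 41.6%, 38.0% and 34.3%. A −log10 q of at least 2 gave 72.0%, 60.2% and 71.8%, with an X ratio of 0.228 (0.22843), and of at least 5 gave 85.2%, 71.7% and 96.8%, with 33.8% TSS-proximal and an X ratio of 0.236. The 20000 strongest regions gave 86.3% and 82.6%, with X ratios of 0.201 and 0.223. Pooled regions in both replicate lists by 50% of either region were 53.7%, the value to set beside 54.7% and 34.3%. TSS windows of 500 bp and 2.5 kb gave 25.5% and 37.3% TSS-proximal, by construction. Leaving out a replicate gave 23.1 to 24.4% TSS-proximal and an X ratio of 0.213 to 0.214, and the pooled list 22.5% and 0.219. No joining gave 2014 domains, and the 200 bp around the summit 0 words. The cause was not tested for the other moves. The test of replicate-specific TSS regions could not pass under any setting (smallest possible adjusted p 0.115 to 0.568, Fisher's exact test), so it says nothing about stability. The macrophage median passed in the pooled list alone (permutation, adjusted p = 0.0490). Read depth is unknown, so its limit on weak regions could not be assessed. Scaffolds changed no share of shared or kept regions by more than its interval. Counting every entry could change nothing, since no position was repeated.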

Other observations

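The 8 gene lists of this part were chosen only after the region lists had been seen, so their tests are not independent of the data.

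Genes that respond within minutes to stimuli had acetylated promoters and wide regions. The 26 immediate early genes had a median of 7.99 kb covered around the TSS (6.72 kb in replicate 1 and 7.44 kb in replicate 2), 4.04-fold the random median, with 29.6 kb at Mcl1, 23.6 kb at Zfp36l1 and 18.5 kb at Ier2. Of these, 25 had a TSS region, and their TSS regions were wider than those of random genes (median 2.47 against 1.49 kb; permutation, two-sided, adjusted p = 0.0224). The widest replicated regions of all lay at Junb (21.1 kb), Ahsg (18.5 kb) and Irf2bp2 (16.9 kb). Junb, Zfp36 and Btg2 were left out of the list because their regions had drawn attention to it. Genes of insulin and growth hormone signalling had 9.14 kb (4.74-fold), with 18.2 kb at Foxo3, 14.7 kb at Igfbp1 and 14.2 kb at Stat5b, and also had wide TSS regions (2.64 kb; permutation, adjusted p = 0.0256). Both lists had an adjusted p of 0.0008 for coverage (permutation, two-sided).

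Clock and lipid genes were also well covered against random lists of protein-coding genes. By the same measure, the ribosome and housekeeping list had 5.91 kb. The circadian median lay above this value and those of the other lists in this paragraph below it, and these differences were not tested. The circadian list had 7.62 kb (3.93-fold; permutation, adjusted p = 0.00427), led by Nr1d1 with 24.2 kb, Per2 with 18.6 kb and Per1 with 16.2 kb. Autophagy and lysosome genes had 5.79 kb (adjusted p = 0.0200, permutation), led by Sqstm1, Npc1 and Ctsd with 19.6, 17.2 and 16.6 kb. Acute phase genes had 5.88 kb, fatty acid and triglyceride synthesis 5.27 kb and cholesterol synthesis and uptake 5.004 kb (each adjusted p = 0.0357, permutation). Their leading members were Cp (13.7 kb), Dgat2 (27.7 kb) and Ldlr (12.1 kb). TSS regions were present at 20 of 20 cholesterol, 17 of 17 fatty acid, 19 of 19 autophagy and 16 of 17 circadian genes, but at 10 of 15 acute phase genes (Fisher's exact test, two-sided, adjusted p = 0.447). The width of the TSS regions of cholesterol genes did not differ from that of random genes (median 1.30 against 1.48 kb; permutation, adjusted p = 0.602), while those of fatty acid synthesis were wide (2.53 kb; permutation, adjusted p = 0.0331). The difference between these lists was not tested. Interferon response genes had 3.56 kb (1.79-fold; permutation, adjusted p = 0.218), with 13.3 kb at Irf9. They had TSS regions more often than other genes, at 15 of 17 (88.2%; Fisher's exact test, two-sided, adjusted p = 0.00735).

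Of the genes with a TSS region in both replicate lists, 97 of 12128 had none in the replicated list, and 88 of the 97 had one in the pooled list. In turn, 171 genes had a replicated TSS region without one in both replicate lists. Of the replicated regions, 7985 (12.4%) were not in both replicate lists by an overlap of 50% of either region, while all 56397 pooled regions that were in both by that measure were in the replicated list.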
